A study of Mus musculus with 2 samples.

How the data were processed

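Long-read RNA sequencing (PacBio) was carried out on total RNA from tissue labelled as a layer of hippocampus, from 8-month-old mice of the 5xFAD strain, with SIRV and ERCC (Ambion mix 1) RNA added as spike-ins. The labels give 2 samples in 1 group, numbered as biological replicates 1 and 2. They have separate biosample records and share a donor record, which names the strain. No control group was analysed here. The free-text description gives the sex as male, while the field for sex was not collected.

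The values are counts of reads per transcript model, deposited as whole numbers in 1 table per library, and per the file headers and the accompanying notes they were made from a filtered mm10 alignment and the GENCODE M21 annotation. Rows with 0 reads were not listed. A deposited annotation of each library, which names TALON as the source of unannotated models, gave coordinates and intron chains. The aligner and the program versions are not given in the sources used here. The tables name a class for each model: Known, incomplete splice match (ISM), NIC (annotated splice sites in an unannotated combination), NNC (at least 1 unannotated splice site), Genomic, Antisense and Intergenic. No normalisation had been applied.

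Spike-in reads (5071 and 3615) were left out of all mouse values. CPM values are counts divided by all mouse reads of the library and scaled to 1e6; these totals were 2874222 and 2925007. Gene values sum the reads of all classes that the table gave to an annotated gene. Identifiers of unannotated models were numbered separately in each library, so these models were matched by chromosome, strand and exact intron chain. Unannotated single-exon models of a gene were treated as 1 class. Intervals for shares are 95% Wilson intervals, the floor for a count of 0 is 3 reads, and spread is the SD over the 2 libraries. An alternative exon was counted on reads that span it, for annotated internal exons of a fixed gene list with 20 or more spanning reads and 5% to 95% inclusion.

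With 1 group no test between conditions could be made, and the quasi-likelihood test of edgeR, which needs 2 groups, was not run. The libraries were compared with each other. Genes with 20 or more reads summed were tested with Fisher's exact test on the gene's reads against all others, with Benjamini-Hochberg adjustment at 0.05. The log2 ratios are of CPM + 1 (replicate 2 over replicate 1). The replicate spread is the square root of the edgeR common dispersion with TMM factors and an intercept alone. Gene lists were compared with 10000 random lists of the same size, matched on mean expression, and needed 4 members with 20 or more reads. Transcript usage was tested in genes with 50 or more reads in each library by the chi-square statistic with 10000 Monte Carlo permutations, models under 10 reads being pooled.

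The comparisons, gene lists and main alternatives were set before the data were examined. The 32 lists were: CA and dentate excitatory neurons, dentate granule cells, CA1 pyramidal cells, CA2 and CA3 pyramidal cells, inhibitory neurons, astrocytes, oligodendrocytes, oligodendrocyte precursors, homeostatic microglia, disease-associated microglia, reactive astrocytes, interferon response, endothelial cells, mural and fibroblast-like cells, choroid plexus, ependymal cells, striatum, thalamus, neocortex, blood, amyloid processing, genes near Alzheimer risk loci, presynaptic proteins, postsynaptic proteins, immediate early genes, heat shock proteins, respiratory chain (nuclear genes), mitochondrial genome, ribosomal proteins, long noncoding RNAs, an isoform list and sex-linked transcripts. Of 418 genes in the lists, 1 was not found in the annotation.

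Genes named in the report followed a rule set in advance. It takes App, Psen1 and Thy1 first, the sex-linked transcripts, the 10 genes with the highest mean CPM, and the 3 members of each list with the highest mean CPM (5 for disease-associated microglia and reactive astrocytes). It takes the 10 called genes with the largest ratio between libraries and at least 50 reads, and from the isoform list the 12 genes with most reads plus App, Mapt, Snap25, Clta, Gfap, Apoe and Trem2. It also takes the 10 unannotated spliced models and 5 antisense or intergenic models with most reads, the 5 genes with the largest usage change, and the 5 genes with most reads among those dominated by unannotated spliced models. Exons named in other genes, and further genes that the text points out, were chosen after their values were seen.

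Alternatives covered the pseudocount, read minimums, TMM and DESeq2 size factors in place of library totals, the classes counted, depth matched by thinning, the rule for matching models, the share that counts as in use, and leaving out each library. Restriction to genes of 1500 bases or more, random lists matched on length, removal of a lowess trend with length (span 0.3), and counts over a locus whatever the gene were added after the data were seen. No paired analysis was possible because there is 1 group.

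The tests were run on simulated data with known changes. Fisher's exact test recovered 26.9% of genes changed 1.5-fold, 59.4% of those changed 2-fold and 87.9% of those changed 4-fold. Among its calls 6.78% were false. These counts were drawn with counting error alone, while the real libraries differed by more. The false share is therefore not that of the calls between the real libraries. The common dispersion returned a coefficient of 0.300 where 0.3 had been set. The list comparison gave p under 0.05 for 8% of unchanged lists and for 100% of lists lowered by 0.5 on the log2 scale. The usage test recovered 79.5% of genes with 20 points moved, with 3.05% false among its calls. The programs were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.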

Results

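Long-read RNA sequencing was carried out on hippocampus of 8-month-old mice labelled male and of the 5xFAD strain. This strain carries human amyloid precursor protein and presenilin 1 transgenes with familial Alzheimer's disease mutations and is used as a model of amyloid deposition. The labels give 1 group of 2 biological replicates and no control group. Values are therefore levels in this tissue, with the spread between the libraries, and every test below compares library with library and not a disease state with a control. Each read was counted once, on the transcript model it was assigned to. Replicate 1 held 2874222 reads on mouse models and replicate 2 held 2925007, and 3 reads corresponded to 1.04 and 1.03 CPM, the read count scaled to a common library size. Reads fell on 222120 and 225008 models, of which 58.4% and 57.3% held a single read. The read-weighted mean model length was 2491 and 2573 bases. Intervals of shares and odds ratios, floors and Fisher's exact tests cover counting error only, and all tests were two-sided. Intervals of medians are bootstraps over models or genes within these 2 libraries, and do not cover variation between animals.

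The mouse counterparts of the transgenes were examined first. App, the mouse amyloid precursor protein gene (chr16:84954443-85173758 for its leading model, mm10), held 3620 and 3854 reads, or 1289 ± 41.1 CPM (SD, n = 2). Psen1, a catalytic subunit of gamma-secretase, held 223 and 237 reads, or 79.3 ± 2.43 CPM. Neither was called different between the libraries by Fisher's exact test (adjusted p = 0.210 and 0.883). The 16-exon model App-201 held 77.3% of App reads in replicate 1 (95% Wilson interval 75.9 to 78.6) and 71.1% in replicate 2 (69.6 to 72.5). Suffix fragments, which match the 3' part of an annotated intron chain, made up 12.6% and 20.0%. With incomplete splice matches left out, the App-201 share was 89.9% ± 0.442. Psen1-201 held 78.5% and 69.2% of Psen1 reads. Reads of the human transgenes were not separated from those of mouse App and Psen1. The levels, model shares and exon inclusion of both genes are therefore those of reads assigned to them, whatever their origin.

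App exons were resolved on single reads that spanned them. The 168-base exon at chr16:85043576-85043743, at the position of the Kunitz protease inhibitor domain, was included in 4.47% (3.81 to 5.23) and 4.35% (3.71 to 5.10) of spanning reads. The 57-base exon at chr16:85040251-85040307 was included in 1.53% and 1.59%. The 54-base exon at chr16:84971408-84971461 was included in 97.7% and 97.9%. Most App reads therefore lacked both the 168-base and the 57-base exon.

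Thy1 (chromosome 9) encodes a neuronal surface glycoprotein, and its regulatory sequence drives the transgenes of this strain. It held 245 and 179 reads, but only 4 and 3 of them matched the full-length model Thy1-201. The rest were almost all single-exon reads over its last exon (chr9:44047339-44048574), at 96.7% (93.7 to 98.3) and 98.3% (95.2 to 99.4) of the gene's reads. The same share was 1.77% and 1.53% for App. Over 7039 genes with 100 or more reads and a multi-exon model, its median was 2.18%, and 8 genes, Thy1 included, were at or above the Thy1 value. The table named these models Genomic in replicate 1 and incomplete splice match in replicate 2. Reads of the transgenes were not separated from those of Thy1 either. The Thy1 values are therefore those of reads assigned to it, whatever their origin.

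Sex-linked transcripts served as a check of the labels. Xist, the long noncoding RNA of the inactive X chromosome, had 0 reads in both libraries. The Y-linked genes Ddx3y (98 and 125 reads), Eif2s3y (147 and 101), Kdm5d (14 and 18) and Uty (8 and 17) were read in both.

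Among all genes, Hspa8, a constitutive heat shock protein, had the highest level with 11792 ± 217 CPM (SD, n = 2). Mbp, a structural protein of myelin, had 6711 ± 46.1 CPM and Trf, which encodes transferrin, 6663 ± 666. Apoe, the main apolipoprotein of brain, had 6528 ± 2313 and Cpe, a carboxypeptidase of neuropeptide processing, 6231 ± 186. Cd81 (5019 ± 879 CPM), Pkm (4590 ± 107), Ctsb (4417 ± 873), Fth1 (4169 ± 2220) and Snap25 (4070 ± 537) completed the 10 highest. Within this set, Apoe was lower in replicate 2 (8164 against 4893 CPM, log2 ratio -0.74), as was Fth1, the ferritin heavy chain (5738 against 2599 CPM, log2 ratio -1.14). Ctsb, a lysosomal protease, was higher (log2 ratio 0.41, adjusted p = 1.44e-108, Fisher's exact test). Cd81 (log2 ratio 0.36), Snap25 (0.27), Trf (0.20), Cpe (0.06) and Hspa8 (0.04) were also called higher, and Mbp and Pkm were not called. Protein-coding genes held 98.8% ± 0.0943 of the reads on annotated genes and lincRNAs 0.274% ± 0.0112.

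Microglial genes were read in both libraries. The 25 disease-associated microglia genes summed to 21095 ± 4074 CPM (SD, n = 2), against 3721 ± 309 for 14 homeostatic microglia genes. Much of the first sum came from Apoe, Ctsb, Fth1 and Ctsd (3079 ± 293 CPM), which other brain cells also express, and from Ctsz (590 ± 6.35 CPM). Among members more restricted to microglia, Trem2, a lipid receptor, had 138 ± 48.3 CPM and Cst7, a cystatin, 117 ± 46.6. Spp1 had 167 ± 4.27 CPM, Clec7a 33.6 ± 4.71 and Itgax 20.5 ± 7.31. Among homeostatic genes, Hexb had 1787 ± 41.9 CPM, and the complement genes C1qc and C1qa had 617 ± 91.8 and 401 ± 154. Tmem119 had 111 ± 0.400 CPM and P2ry12 118 ± 17.8. The members named after Ctsz other than the complement genes and Hexb were chosen after their values were seen. Without a control group these levels cannot be set against tissue free of amyloid.

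Astrocyte genes summed to 9457 ± 435 CPM, led by Aldoc (3907 ± 342), Sparcl1 (3033 ± 51.5) and Slc1a3 (656 ± 48.0), a glutamate transporter. Reactive astrocyte genes summed to 2824 ± 295 CPM. Gfap, an intermediate filament of astrocytes, accounted for most of it at 1673 ± 116 CPM. H2-D1 followed with 583 ± 98.1 CPM, C4b, a complement component, with 152 ± 45.7, H2-K1 with 106 ± 22.8 and Vim with 84.4 ± 10.1. Interferon response genes summed to 833 ± 162 CPM, with Ifit3 at 503 ± 113, Ifit1 at 96.5 ± 31.7 and Stat1 at 90.1 ± 15.7.

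Neuronal lists covered hippocampal cell types and neighbouring regions. Genes of excitatory neurons summed to 6669 ± 626 CPM (Ppp3ca 2665 ± 311, Chn1 1569 ± 71.3, Gria2 971 ± 110). Dentate granule cell genes summed to 841 ± 3.10 CPM, led by Calb1 (370 ± 59.0), C1ql2 (249 ± 37.1) and Stxbp6 (99.3 ± 7.06). CA1 genes summed to 364 ± 11.8 CPM (Mpped1, Wfs1 and Fibcd1 led) and CA2 and CA3 genes to 378 ± 15.6 (Necab2, Amigo2 and Cpne4 led). Inhibitory neuron genes summed to 793 ± 58.5 CPM (Gad1 365 ± 30.8, Slc6a1 174 ± 42.2, Cck 87.8 ± 38.2). Among regions near the hippocampus, the neocortex list summed to 257 ± 0.506 CPM (Etv1, Lamp5 and Fezf2 led), the thalamus list to 195 ± 11.5 (Rora, Calb2 and Prkcd) and the striatum list to 170 ± 0.0870 (Ppp1r1b, Penk and Pde10a).

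Oligodendrocyte genes summed to 16769 ± 690 CPM, from Mbp, Trf and Cnp (1166 ± 65.4 CPM) among others. Their precursors summed to 276 ± 10.7 CPM (Olig1, Olig2 and Ptprz1 led). Endothelial genes summed to 2696 ± 41.7 CPM, of which Bsg held 2106 ± 4.16, ahead of Cldn5 and Itm2a. Mural and fibroblast-like cell genes summed to 243 ± 1.79 CPM (Dcn, Rgs5 and Vtn led). The choroid plexus list summed to 445 ± 11.6 CPM, of which Enpp2 held 398 ± 9.71, Ttr, the plexus transthyretin gene, 29.9 ± 17.7 and Clic6 3.79 ± 0.929. Ependymal genes (Rarres2, Tekt1 and Tmem212 led) summed to 13.8 ± 5.05 CPM and blood genes (Hbb-bs, Hba-a1 and Hba-a2 led) to 45.5 ± 29.1.

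**Figure D1:**
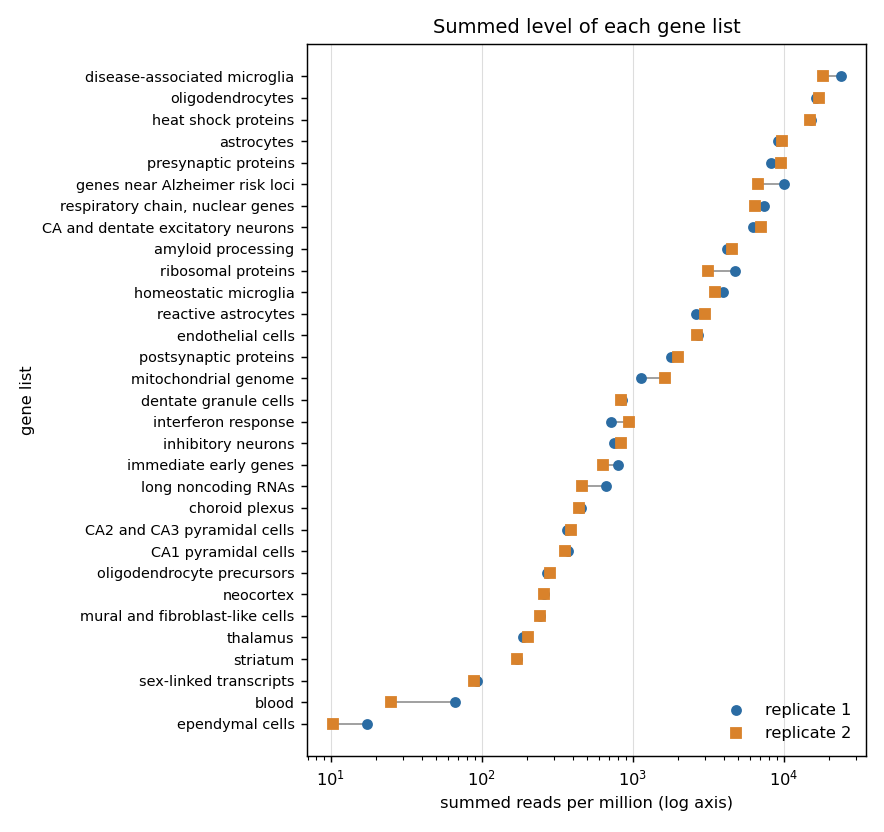
Summed CPM of each gene list (log axis) in replicate 1 (circles) and replicate 2 (squares) of 5xFAD hippocampus, with lists ordered by their mean. Disease-associated microglia genes have a mean sum of 21095 CPM and oligodendrocyte genes of 16769 CPM, and the blood list has 66.1 and 24.96 CPM in the libraries.

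Genes of amyloid processing summed to 4367 ± 231 CPM. Aplp1 (1410 ± 119 CPM), App and Apbb1 (944 ± 11.0) led. Bace1, the beta-secretase gene, had 103 ± 3.47 CPM. Genes near Alzheimer risk loci summed to 8386 ± 2257 CPM, most of it Apoe. Clu, another apolipoprotein, had 726 ± 48.8 CPM and Ptk2b 251 ± 44.7. Presynaptic genes summed to 8920 ± 899 CPM (Snap25, Rab3a and Syn2 led) and postsynaptic genes to 1896 ± 160 (Camk2b, Dlgap1 and Baiap2). Immediate early genes summed to 713 ± 116 CPM (Junb 340 ± 68.4, Jun 97.8 ± 9.75, Egr4 64.1 ± 14.2) and heat shock genes to 15001 ± 79.5 (Hspa8, Hsp90ab1 and Hspa5). Nuclear respiratory chain genes summed to 6932 ± 659 CPM (Atp5a1, Atp5b and Uqcrc1), transcripts of the mitochondrial genome to 1388 ± 366 (mt-Co1, mt-Rnr2 and mt-Nd4), and 20 ribosomal protein genes to 3941 ± 1143 (Rpl3, Rpl4 and Rps6). Long noncoding RNAs summed to 561 ± 143 CPM, with Malat1 at 200.4 ± 119, Meg3 at 156 ± 6.32 and Snhg11 at 135 ± 10.2.

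Most reads carried an annotated transcript structure. Known models held 73.3% ± 1.45 (SD, n = 2) of the reads, 74.4% and 72.3% per library. Incomplete splice matches (ISM), whose intron chain is part of an annotated one, held 10.1% ± 0.967, mostly as 3' suffixes (6.30% ± 1.01). Models that join annotated splice sites in an unannotated way (class NIC) held 5.96% ± 0.0437, and models with an unannotated splice site (class NNC) 3.24% ± 0.0329. Genomic models, which are almost all unspliced, held 4.22% ± 0.375, antisense models 2.72% ± 0.144 and intergenic models 0.377% ± 0.0224. Of annotated genes, 18993 and 18714 were detected, 16943 of them in both libraries.

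**Figure D2:**
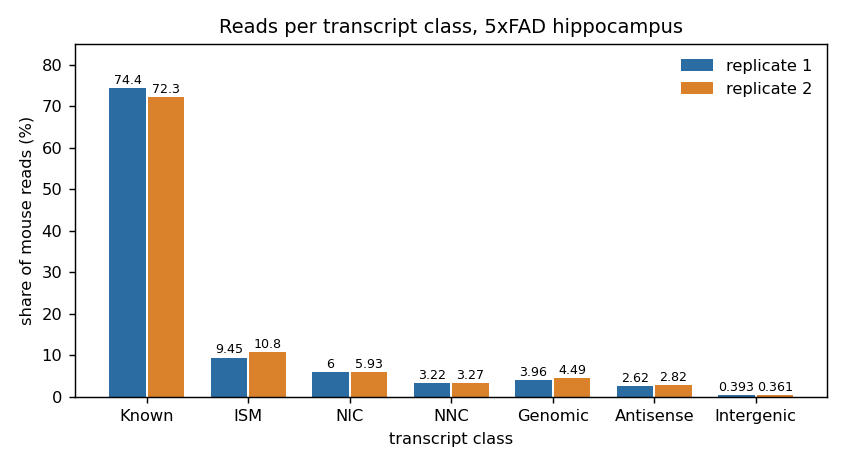
Share of mouse reads (%) in each transcript class, for replicate 1 and replicate 2 of 5xFAD hippocampus; each bar is 1 library and the number above it is its share. Known models hold 74.4% and 72.3%, and incomplete splice matches (ISM) 9.45% and 10.8%.

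Unannotated spliced models of classes NIC and NNC were compared between the libraries. Matched by intron chain, 29765 models were found in both, of 86080 in replicate 1 and 87491 in replicate 2. In replicate 1, 43.8% of NIC and 26.2% of NNC models were shared. Among those with 5 or more reads the shares were 95.4% and 94.98%, and among those with 1 read 25.4% and 15.4%.

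In 951 genes, 255 of them with 50 or more reads in each library, such models held most of the reads in both libraries. In Oaz1, the antizyme gene regulated by translational frameshifting, they held 99.5% ± 0.101 (SD, n = 2). Of the gene's reads, 96.5% ± 0.597 were on 1 NIC model of 5 exons (chr10:80826656-80829284), with 7824 and 4819 reads and no unannotated intron. Other such genes with the most reads were Hnrnpk, an RNA-binding protein (95.3% ± 0.642), Klc1, a kinesin light chain (59.9% ± 0.730), Apbb1, an adaptor that binds App (76.6% ± 1.51), and Ttc3 (59.6% ± 11.3). The leading Apbb1 model (chr7:105558483-105581192, 14 exons) held 55.1% ± 0.714 of the gene's reads. Further abundant models lay in Ctbp1 (58.1% ± 0.0636 of the gene's reads), Atp2b1 (56.0% ± 2.39), Sept7 (76.1% ± 2.30), Ptov1 (72.6% ± 1.02), Oaz2 (89.6% ± 0.546), Pls3 (72.2% ± 1.29) and Hnrnpk (39.3% ± 0.151). The leading NNC model, in the vesicle GTPase gene Rab3a, held 29.3% ± 0.177 and used an unannotated intron at chr8:70754870-70755855.

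Single-exon antisense models held many of the reads outside annotated genes. The one with most reads in replicate 2 lay opposite Map1b (chr13:99421446-99424415, + strand) with 4878 reads, and its counterpart in replicate 1 had 2868, against 4911 and 4686 reads of Map1b itself. Antisense models opposite Snhg11 held 1544 and 1614 reads, more than the 409 and 374 reads of that gene. Opposite Rab11fip4 there were 1414 and 1892 reads against 35 and 38 of the gene itself. Models opposite Gm26917 held 3196 and 1710 reads, against 109 and 76. The model opposite Slc1a2, an astrocyte glutamate transporter, held 1192 in replicate 1, against 1068 reads of that gene. In replicate 2 it held 1400, fewer than the 1482 reads of the gene. The model opposite Tmem170b held 1452 in replicate 2, against 37.

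Transcript choice within genes was examined where a gene had 50 or more reads in each library. Of 6970 such genes, 2805 (40.2%) used 2 or more models at 10% or more of their reads in each library, and 577 used at least 3. These counts include incomplete splice matches and unannotated single-exon models. With Known, NIC and NNC models alone, 1838 of 5722 genes used 2 or more. Mbp was led by Mbp-211 (69.2% ± 0.645), Mbp-212 (16.6% ± 0.614) and Mbp-215 (7.02% ± 0.0662). Ppp3ca, the calcineurin catalytic subunit, divided between Ppp3ca-201 (59.8% ± 0.676) and Ppp3ca-202 (30.9% ± 0.932). Ndrg2-202 held 49.7% ± 0.686 and Ndrg4-202 61.6% ± 3.04. Single models led in Apoe (Apoe-206, 96.3% ± 0.613), Calm2 (97.4% ± 0.366), Calm1 (97.4% ± 0.0477), Hexb (97.2% ± 0.372) and Ctsd (91.4% ± 1.84). Gfap-201 held 75.6% ± 0.560 and Gfap-202 6.45% ± 0.585. Trem2-201 held 80.2% ± 3.16, and Trem2-202, which also has 5 exons, 14.5% ± 0.843.

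Alternative exons were counted on reads that spanned them. Over 89 exons in 36 genes, the median difference was 1.86 percentage points. By Fisher's exact test with Benjamini-Hochberg adjustment 0 exons differed (smallest adjusted p = 0.390); 6 had an unadjusted p under 0.05. Snap25, a vesicle fusion protein, used the first of its mutually exclusive 118-base exons (chr2:136769743-136769860) in 8.23% ± 0.607 of reads and the other (chr2:136770057-136770174) in 91.7% ± 0.596. The AMPA receptor genes Gria2 (- strand) and Gria1 (+ strand) each have alternative 115-base exons. In Gria2 the upstream exon (chr3:80691320-80691434) was used in 64.0% ± 0.423 and the downstream exon (chr3:80690404-80690518) in 35.9% ± 0.348. In Gria1 the upstream exon (chr11:57309769-57309883) was used in 71.4% ± 1.12 and the downstream exon (chr11:57310608-57310722) in 27.2% ± 1.23. Pkm used its alternative 167-base exons in 82.6% ± 0.227 and 17.3% ± 0.249. In Mapt, the tau gene, the 93-base exon at chr11:104318157-104318249, which encodes a microtubule-binding repeat, was included in 99.4% and 99.1%. The 87-base Mapt exons at chr11:104287123-104287209 and chr11:104289908-104289994 were included in 22.0% ± 0.212 and 12.99% ± 1.501. In Clta, a clathrin light chain, the 54-base and 36-base exons were included in 69.8% ± 3.15 and 66.9% ± 3.42. Bin1, near an Alzheimer risk locus, included its exon at chr18:32414945-32415037 in 52.2% ± 2.12. Grin1, an NMDA receptor subunit, included its 63-base exon (chr2:25311343-25311405) in 13.4% ± 0.887.

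**Figure D3:**
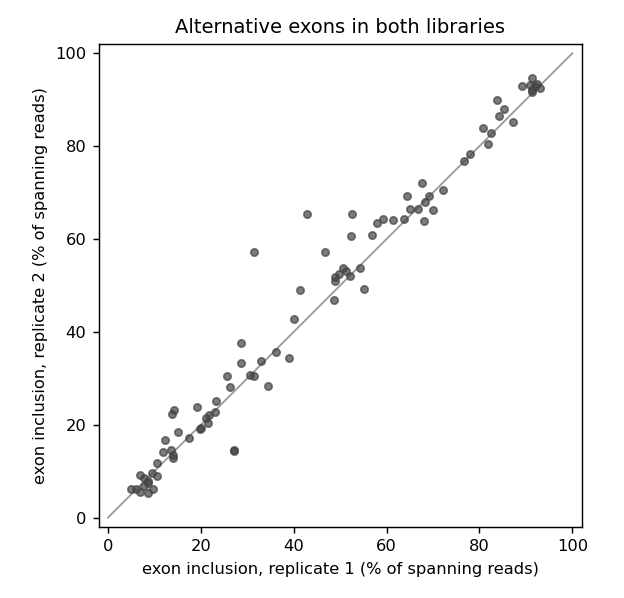
Inclusion of each of 89 alternative exons (% of reads that span it) in replicate 1 (x axis) and replicate 2 (y axis); each point is 1 exon and the line marks equal values. Points lie near the line, with a median difference of 1.86 percentage points, and the largest difference, 25.7 points, is in a Meg3 exon.

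The libraries were then compared gene by gene, to see how far levels differed beyond counting error. Across 12149 genes with 20 or more reads, Pearson's r of log2(CPM + 1) was 0.965 and Spearman's rho 0.963; genes are not independent replicates. The chi-square of the gene counts was 6.403 per degree of freedom, so the tables differed by more than counting error. Fisher's exact test called 1700 genes after Benjamini-Hochberg adjustment, 762 higher and 938 lower in replicate 2, and 2941 had an unadjusted p under 0.05. A change of 2-fold or more was seen in 474 of them, 125 higher and 349 lower. The edgeR common dispersion gave a biological coefficient of variation of 0.176. With genes of mean model length of 1500 bases or more alone, a choice made after seeing the data, 960 genes were called, 651 higher and 309 lower.

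Known models of 500 to 1000 bases were lower in replicate 2. Those of 750 to 1000 bases had a median log2 ratio (replicate 2 over replicate 1) of -0.65 (95% bootstrap interval -0.71 to -0.59), and those of 500 to 750 bases -0.60. Models under 500 bases had -0.22, and those of 1000 to 1500 bases -0.17 (-0.20 to -0.14). The fall was in models of the GENCODE basic set without a tag for a missing end, with medians of -0.82 at 750 to 1000 bases, -0.90 at 500 to 750 and -0.46 below. The remaining models had -0.20, -0.02 and 0.07 in these bins. Models of 2000 to 3000 bases had a median of 0.0045.

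**Figure D4:**
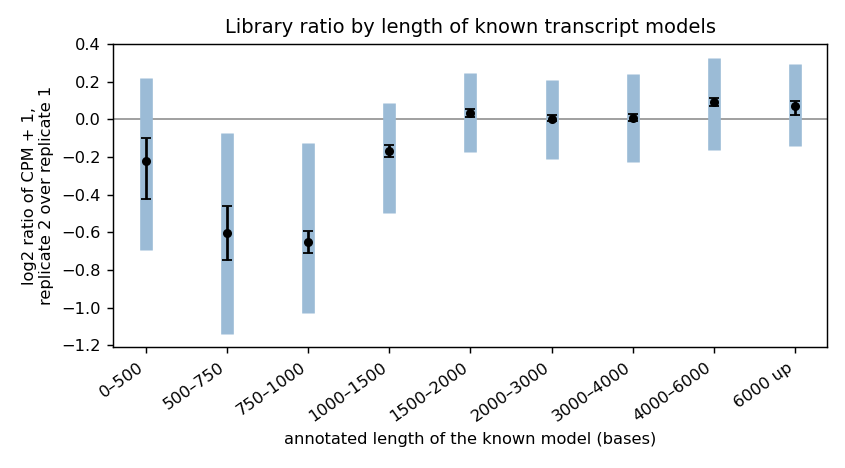
Log2 ratio of CPM + 1 (replicate 2 over replicate 1) of known transcript models, by annotated length in bases; points are medians, thin bars their 95% bootstrap intervals and thick bars the quartiles. The median is -0.65 for models of 750 to 1000 bases and near 0 above 1500 bases.

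Of the 30 gene lists with at least 4 measured members, 5 stood apart from random lists matched on expression. Ribosomal protein genes were lower in replicate 2, with a median log2 ratio of -1.09 (adjusted p = 0.0030, 10000 random lists). Of 20 members, 17 were lower, and 18 when adjusted over the list alone; Rps6 (log2 ratio -1.22) was among them, and Rpl4 had -0.07. Nuclear respiratory chain genes had a median of -0.53 (adjusted p = 0.0030), with 9 of 17 lower and 0 higher (9 and 1 adjusted over the list alone). Cox4i1 had -1.63, Atp5a1 -0.22 and Atp5b 0.08. Blood genes had -1.26 (adjusted p = 0.0060), with 3 of 4 lower by either adjustment. Disease-associated microglia genes had -0.13 (adjusted p = 0.049), with 7 of 24 lower and 2 higher (8 and 3 adjusted over the list alone). Apoe, Fth1 and Ctsd were lower in that list and Ctsb was higher, and Ctsz had a log2 ratio of 0.02 (adjusted p = 0.875). The list's call ended with denominators scaled by the trimmed mean of M values (TMM), at a median of -0.16 (adjusted p = 0.058). It also ended without genomic and ISM reads, at a median of -0.12 (adjusted p = 0.088). Presynaptic genes were higher, with a median of 0.26 (adjusted p = 0.0060), and 9 of 16 were higher and 2 lower (10 and 3 adjusted over the list alone). Snap25 (log2 ratio 0.27) and Rab3a (0.27) were among the higher members, and Syn2 had 0.02. Without genomic and ISM reads the call ended (median 0.0023 over 13 members, adjusted p = 0.719).

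Transcript length differed between these lists. The median over members of mean model length was 814 bases for ribosomal proteins, 756 for the respiratory chain, 663.5 for blood and 1416 for disease-associated microglia, against 2117 for presynaptic genes. With random lists matched on length as well, which was chosen after seeing the data, ribosomal (adjusted p = 0.0030) and presynaptic genes (0.0080) stood apart. The microglia (adjusted p = 0.630), respiratory chain (0.262) and blood lists (0.095) did not. Mitochondrial genome transcripts, at a median log2 ratio of 0.22, then stood apart as higher (adjusted p = 0.0030), with mt-Co1 at 0.63 and 4 of 11 members higher by either adjustment. In the matching on expression, 25 of the 30 lists did not pass the threshold, among them homeostatic microglia (median -0.03, adjusted p = 0.661), astrocytes (-0.12, adjusted p = 0.200), reactive astrocytes (0.19, adjusted p = 0.232), interferon response (0.14, adjusted p = 0.592) and immediate early genes (-0.25, adjusted p = 0.133). With members of 100 or more reads alone, 9 lists passed, the last 3 of these among them with inhibitory neurons and the mitochondrial genome, and without blood, which had too few such members. The choroid plexus and ependymal lists had too few members with 20 reads to be tested.

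The genes with the largest ratios were Klhl10 (3 against 805 reads), Vil1 (0 against 212), Pcdhga2 (240 against 2), Gm26786 (0 against 93), Gm48993 (88 against 0), Gm49326 (88 against 0), Sowahb (26 against 593), Gm48770 (51 against 0), Gm26848 (2 against 88) and Yjefn3 (163 against 7). For 8 of these 10 genes, reads over the leading model on the same strand, whatever gene they had been assigned to, differed less than 2-fold. For Klhl10 they numbered 531 and 796, over a model (chr11:100457022-100461670) that starts at the last annotated base of the gene. The leading models of Sowahb (chr5:93170504-93172588), Gm48993 (chr14:111675097-111680175) and Gm48770 (chr13:36088144-36117412) lay outside the annotated gene. These counts are therefore of reads assigned to the named genes and not always of reads within them. Gm49326 and Sowahb were the exceptions.

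Transcript usage differed between the libraries in 252 of the 6970 genes (3.62%) by a Monte Carlo permutation chi-square test with Benjamini-Hochberg adjustment, and 128 of them moved by 10 percentage points or more in 1 model. With Known, NIC and NNC models alone, 117 of 5722 genes differed, 50 of them among the 252. The largest changes were in Ndufb2 (unannotated single-exon models 12.9% against 86.4% of reads), Pcdhgc5 (1.65% against 65.4%), Gprasp1 (3% against 49.8%), BC065397 (44.7% against 0.810%) and Smpd3 (41.2% against 4.35%), each with p = 0.0001, the smallest these permutations can give (adjusted p = 0.0055). In each of these 5 genes the class with the largest change was unannotated single-exon models. For Pcdhgc5, Ndufb2 and Smpd3, reads at the locus had been given to different genes in the libraries. Over the leading Pcdhgc5 model 483 and 531 reads lay on the same strand whatever their gene, and Pcdhga2 held 239 of those in replicate 1. Over that of Ndufb2 there were 151 and 294, and in replicate 1 an antisense gene held all 151. Over that of Gm26786, which overlaps Smpd3, there were 139 and 196, and Smpd3 held all 139 in replicate 1. For Gprasp1 the counts were 376 and 537, with 201 of the former on Gprasp1 itself and the rest on other genes. Reads at the BC065397 locus were not counted in this way.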

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

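Of the tests in this part, the comparison of transcripts within genes and the test for reverse copies were set before their results were seen; the repeat within genes over complete models, the spike-in, list, locus and both orientation tests were chosen after the result was seen. No biological explanation was tested, because the design gives 1 group.

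Reads on genes that the annotation lacks were outside the main comparisons and far above the limit that a count of 0 allows. Antisense gene models held 2.70% of mouse reads in replicate 1 and 2.996% in replicate 2, and intergenic gene models held 0.414% and 0.380%.

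Single-exon models antisense to annotated genes with 50 or more reads lay at 123 and 142 loci. The 142 loci leave out the replicate 2 model opposite Gm26917 (1710 reads). Of the loci counted, 95.9% and 95.1% had reads in the other library. Reads written in the wrong orientation at the rate of the ERCC spike-ins are argued against. The spike-ins had 1.99% (95% Wilson interval 1.58 to 2.502) and 1.31% (0.923 to 1.85) of their reads on the wrong strand. Against sense reads that cover at least 50% of the model, the median share of antisense reads at these loci was 100%. At 65 and 80 of the loci there was no such sense read. Against every read of the genes opposite, the median share was 60.7% and 58.6%. The loci were selected for their antisense reads, so a higher rate of wrong orientation at single loci was not excluded. Reverse copies of complete sense transcripts stay open. At most 28.8% of the antisense reads were on models whose 5' end lay within 50 bases of an annotated 3' end on the other strand. This is between the bounds of 20% and 50% set for the test. The ends of single reads were not examined. In replicate 2 the model opposite Map1b, which is among these, alone held 4878 of the 33094 reads. Priming inside transcripts was not checked, since the genome sequence was not at hand.

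Known models of 500 to 1000 bases and lists of short genes were lower in replicate 2. The fall was smaller for models under 500 bases (median log2 ratio -0.22) and of 1000 to 1500 bases (-0.17). It was also smaller for models outside the complete set (-0.02 at 500 to 750 bases and -0.20 at 750 to 1000). Within genes that have both, known models under 1000 bases did not fall against models over 1500 bases (median log2 difference -0.0374, 95% interval -0.127 to 0.0419, 551 genes; -0.0525, -0.176 to 0.0522, over 170 genes with complete models), both above the bound of -0.2 set for the test, which argues against a length bias that acts on every model alike. ERCC spike-ins under 750 bases, which no cell regulates, held relatively fewer reads in replicate 2 (odds ratio 0.650, 95% interval 0.490 to 0.862, p = 0.00277, Fisher's exact test). They were 10 species with 164 and 72 reads, against 3404 and 2298 reads on longer ones. The test and its interval cover counting error only, and single species were not compared. A technical part is therefore possible but not shown. Removing the length trend moved the disease-associated microglia median from -0.13 (SD 0.546) to -0.00598 (SD 0.424) and the respiratory chain median from -0.53 (SD 0.553) to 0.000386 (SD 0.416), near the level of random lists, and their calls ended, as did that of blood, whose median stayed lower (-1.26, SD 0.459, before and -0.360, SD 0.262, after, adjusted p = 0.611). The ribosomal protein median moved from -1.09 (SD 0.472) to -0.448 (SD 0.603), and its call stayed (adjusted p = 0.0030, random lists). This argues against the trend fitted over all genes as the whole cause there. The same held for presynaptic proteins (0.26, SD 0.303, before and 0.210, SD 0.291, after, adjusted p = 0.016, random lists). Complete known models fell more, with medians of -0.90 at 500 to 750 bases and -0.82 at 750 to 1000. The correction did not separate complete from other models. A length effect of complete short models was therefore not excluded for the ribosomal list. Without genomic and ISM reads the ribosomal call stayed (median -1.06, adjusted p = 0.0029, random lists). The presynaptic call ended there (median 0.0023 over 13 members, adjusted p = 0.719, random lists). The presynaptic list is therefore weaker evidence of a difference beyond the fitted trend. A bias in preparation and a difference between the tissues both stay open.

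The largest ratios between the libraries mostly belonged to loci whose reads had been given to different genes. For 8 of the 10 genes, reads over the leading model differed less than 2-fold whatever their gene, consistent with separate assignment in each library as their source. At the Pcdhga2 locus, for example, 483 and 531 reads were counted, of which Pcdhgc5 held 300 in replicate 2. The other 2 genes passed 2-fold by this count, but reads there had changed gene too. For Sowahb the 269 reads of replicate 1 were on an antisense gene, against 579 in replicate 2 (2.11-fold), and Gm49326 had 76 and 2 over its own leading model but 77 and 51 over that of Gm49329, which starts at the same base, with all 77 on Gm49326.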

How the results depend on the processing

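The length restriction, the length-matched and length-corrected lists and the locus counts were chosen after seeing the data; the other alternatives were planned. A count was taken as the same within 1.5 times, a share within 1 SD, r within its 95% interval and the coefficient of variation when equal to 2 digits, so r and the coefficient were held to a narrower tolerance than counts. By these criteria 31 of 58 alternative values were the same and 27 moved. Of the 31, the 4 shares with a replicate left out are no evidence, since with 2 libraries each lies within 1 SD by construction. Counts were compared by their totals alone, which hides a turn in direction. The cause was not tested unless stated. The share of reads on known models was 75.8% over annotated nuclear genes and 83.5% with incomplete splice matches counted as known, and 72.3% to 74.4% with each replicate left out. Unannotated spliced models in both libraries numbered 5206 with at least 5 reads in each and 0 by identifier, since identifiers are numbered per library; single libraries held 86080 to 87491. Genes detected in a single library ranged from 18714 to 18993. Pearson's r was 0.958 with a pseudocount of 0.1 CPM, 0.977 with 10 CPM, 0.978 with at least 1 read, 0.957 with at least 100 reads and 0.945 for transcript models. Genes that differed between libraries numbered 960 among those of 1500 bases or more (651 higher and 309 lower, where the full set had 762 and 938), 474 with a 2-fold change, and 414 with a 2-fold change kept by all reads at the locus; fewer genes qualify by construction. The coefficient of variation was 0.0001 from the DESeq2 median gene-wise dispersion, which is the lower limit of that tool and not an estimate, 0.168 with at least 100 reads and 0.131 for genes of 1500 bases or more. Lists that stood apart numbered 9 with members of 100 or more reads, 3 without genomic and ISM reads (0 higher, where the full set had 1) and 3 with length-matched random lists. With the length trend removed 4 lists stood apart, of which 2 were among the original 5. Genes with at least 2 models in use numbered 1805 of 4724 with at least 100 reads and 1082 of 6970 at 20% of reads. They numbered 3451 to 3585 in single libraries, and 1838 of 5722 from Known, NIC and NNC models alone. Usage differed in 117 genes with those classes alone, 50 of them among the original 252, and in 128 with a change of 10 points required. The App-201 share was 91.5% with those classes alone, 89.9% without incomplete splice matches, and 71.1% to 77.3% with each replicate left out. Leaving out a replicate gives no value for results that compare the libraries. At this depth a count of 0 allows up to 1.04 and 1.03 CPM. Of models with a single read in replicate 1, 25.4% (NIC) and 15.4% (NNC) were found in replicate 2, and the cause was not tested.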

Other observations

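Immunoglobulin transcripts were read in the tissue. Ighm, the constant region of the IgM heavy chain, held 372 and 420 reads, or 137 ± 10.01 CPM (SD, n = 2); it was chosen after its value was seen. All IG constant genes together held 0.0144% ± 0.00101 of reads on annotated genes. Among interferon response genes, Ifit3 (log2 ratio 0.46, adjusted p = 7.44e-16, Fisher's exact test) and Ifit1 (log2 ratio 0.68, adjusted p = 1.11e-06) were higher in replicate 2, while the list as a whole did not pass its test (median 0.14, adjusted p = 0.592) except with members of 100 or more reads alone (0.35 over 7 members, adjusted p = 0.030). Over that list 4 of 10 genes were higher and 0 lower, and 4 and 1 when adjusted over the list alone.

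Thy1 had a single-exon share of 97.4% over both libraries, at percentile 99.9 of 7039 genes with 100 or more reads, while Psen1 had 7.17% and App 1.65%.

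In the main setting neither immediate early genes (median log2 ratio -0.25, adjusted p = 0.133) nor mitochondrial genome transcripts (0.22, adjusted p = 0.253) were called. Both were with members of 100 or more reads alone (-0.35, adjusted p = 0.030, and 0.28, adjusted p = 0.049), and the latter also with length-matched random lists (adjusted p = 0.0030). With the length trend removed, a step chosen after seeing the data, as were the length-matched lists, the medians were -0.33 (adjusted p = 0.016) and 0.82 (adjusted p = 0.0030). The mitochondrial median before that step was 0.22, with 4 of 11 members called higher, so the 0.82 rests largely on the trend subtracted. Length-matched random lists for it had a median of -0.30.

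The isoform list (Mbp, Apoe and Pkm had the most reads) had a median log2 ratio of 0.03 (adjusted p = 0.991), with 21 of 79 genes higher and 12 lower in replicate 2, and 24 and 14 when adjusted over the list alone. The sex-linked list had a median of 0.30 (adjusted p = 0.457), with 1 of 4 genes lower by either adjustment.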
